A study of Mus musculus with 54 samples.

How the data were processed

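RNA sequencing was done on mouse embryonic stem cells (mESC) in the undifferentiated state and after a brief differentiation in which 2i and LIF were removed and all-trans retinoic acid (ATRA) was added, per the labels' protocols. Messenger RNA was selected by its poly(A) tail and copied with random hexamers, per the labels' protocols. Per the submitters' processing notes, cutadapt 3.2, STAR 2.7.3a, featureCounts 1.6.4, DESeq2 1.38.3 and the mm10 genome were used, with no role or order stated. The authors deposited 1 table of raw counts, which holds the count of reads per gene for 55401 versioned Ensembl genes in every library, without normalisation. The annotation release, the strandedness of the libraries and the treatment of reads that map to several places are not given in the sources used here. Gene symbols, positions, types and GC content were taken from GENCODE M21 on GRCm38, in which 55141 of the identifiers were found and 260 were not.

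The series holds 54 samples in groups of 3. Columns of the deposited table were matched to samples by line, state and replicate number, and 48 libraries in 16 groups were matched. A further 6 columns match no label and were left out of every step, so the line labelled Y728 was not analysed here. The plan had a mean over 5 variants that counted Y728, and all of its steps were run with the 4 that remain, which are A677T, R679C, K634E and K563E. The labels do not say which variant is the growth restriction-associated one. A733T was kept apart as that variant from general knowledge of the study. The groups, the comparisons, the tests, the gene lists and the rule for naming genes were fixed before the data were examined.

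Libraries held 15361598 to 31338825 counts. Data were simulated with their depths and spread, 200 genes changed and no GC trend. The test recovered 57% to 86% of genes changed 1.5-fold and 82% to 97% of those changed 2-fold, with at most 10 unchanged genes called. Mitochondrial genes took 1.26% to 2.77% of counts, and the 10 most abundant genes 5.11% to 6.33%. The 48 pairs of libraries of the same group all differed by more than counting error, with a chi-square per degree of freedom from 2.81 to 39.5, so no library is a copy of another of its group. The highest values were those of A677T replicate 3 in mESC (19.9 and 39.5 against the others of its group, which differed from each other at 9.64) and K634E replicate 3 in ATRA (19.9 and 26.7, against 2.86). These libraries had the lowest correlation with GC content in their state (-0.72 and -0.75), the highest mitochondrial shares (2.70% and 2.77%) and, on principal components 2 of mESC and 3 of ATRA, the most extreme values (-46.2 and -44.1). Nothing in the labels says that replicates are separate cultures. The p-values therefore measure only the spread between these samples, which may be technical. Intervals and floors cover counting error only.

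Genes were tested in R 4.3.3 with edgeR 4.0.16, using filterByExpr, TMM normalisation and the robust quasi-likelihood test. Each state was fitted on its 24 libraries with 1 mean per line, which left 16 residual degrees of freedom. The effect of ATRA in the WT line and the interaction of the variants with ATRA were fitted on all 48 libraries. In all, 22 comparisons were tested. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, a gene counts as changed at an adjusted p under 0.05, and levels are TMM-normalised counts per 1e+06 library counts (CPM). Fold changes are log2 values with their standard error (SE).

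Lists of genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, with p adjusted over the 22 lists of a comparison. The same test with a correlation estimated from the data, and fry, were run beside it. The lists held PRC2 and PRC1 subunits, developmental Polycomb targets, Hox genes, naive and primed pluripotency genes, retinoic acid response genes, markers of neuroectoderm, mesoderm, endoderm, trophoblast and fibroblasts, genes of the 2-cell-like state, germline genes, imprinted genes, growth control genes, overgrowth syndrome genes, skeletal genes, p53 and stress genes, interferon genes, proliferation genes, and genes that depend on LIF, ERK or WNT signalling. The lists overlap, and several markers are also expressed in undifferentiated cells. Member counts are given over all genes tested and, where stated, adjusted over the list alone.

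Genes were named by rule among those with an adjusted p under 0.05, a mean of at least 1 CPM in a compared group, no overlap between the libraries of the compared groups, and a symbol that is not a predicted model. For a mean of variants the overlap condition was replaced by the same sign in every variant. By size of change, 10 genes per direction were named for the mean of the 4 variants and A733T against WT in each state and for ATRA against mESC, 3 for each other single variant and 4 for other comparisons. Ezh2, Eed, Suz12 and Ezh1 were named throughout, as were up to 4 members of each list with the lowest adjusted p, and the 5 genes per direction with the strongest call in all 4 variants. In a comparison of 3 with 3 libraries, chance leaves a gene's groups without overlap in 10% of cases. For a gene with 0 counts in a group, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, the ratio is given with the exact 95% counting interval of that count.

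Alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, a replicate block, other sets of libraries in the fit, averaging A733T with the others, and leaving out each library in turn. Chosen after seeing the data were a correction that takes each library's smooth trend over gene GC content out through offsets, the same with the replicate block, the use of replicates 1 and 2 alone, and the imprinted list tested without Meg3, Rian and Mirg in het against parental. Whether replicate numbers pair the libraries was checked from correlations of residuals between libraries with the same number. The result depends on the genes used. Over genes above 4 CPM, all 3 pairs exceeded 0.1 in R679C, K563E and A733T against WT after ATRA, with the lowest pair at 0.437, 0.122 and 0.202, and over all genes only in R679C, with the lowest at 0.189. Blocked values are given where they end a call or move a count by over 1.5 times. With a GC trend simulated too, 3592 unchanged genes (23.5%) were called without the correction and 11 with it. Calls are uncorrected unless stated and may hold such genes. Similarity of variants is the Pearson correlation and the covariance of log2 fold changes across genes. Beside it are 10 simulated sets of unchanged groups sharing a simulated control. Genes are not independent replicates, so similarity has no p-value. With 3 WT libraries the controls could not be divided between the variants.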

Results

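Gene expression was measured by RNA sequencing in mouse embryonic stem cells that carry different forms of EZH2, the catalytic subunit of Polycomb repressive complex 2 (PRC2), which methylates histone H3. The lines analysed were the parental line with both Ezh2 alleles (parental), its heterozygous derivative with 1 allele deleted (het), the het line with added wild-type EZH2 (WT), and the het line with added EZH2 A677T, R679C, K634E, K563E or A733T. Weaver syndrome, the subject of the series, is an overgrowth syndrome caused by EZH2 variants. Each of the 8 lines was sequenced undifferentiated (mESC) and after brief differentiation with all-trans retinoic acid (ATRA), with 3 libraries per group and 48 in all. Libraries held 15361598 to 29614420 counts in mESC and 15612700 to 31338825 in ATRA. Y728 was not analysed.

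Libraries also differed in how counts depended on the GC content of genes. In mESC, the Spearman correlation across genes between GC content and a library's deviation from the mean was 0.49 to 0.72 in WT, 0.33 to 0.47 in het, -0.72 to 0.02 in A677T, -0.71 to -0.26 in K634E, -0.57 to 0.00 in K563E, -0.37 to 0.11 in R679C and -0.06 to 0.40 in A733T. Across genes above 4 CPM, the log2 fold change of the mean of the 4 variants against WT correlated with GC content at -0.65 in mESC and at -0.35 in ATRA, and the value was -0.36 for A733T in mESC. With each library's GC trend taken out, the correlation for the 4 variants in mESC was 0.08. Counts with this correction are given below where they move a count by over 1.5 times or the share of higher genes by over 10 points, or turn which direction has more genes. The correction turned that direction in every comparison but A677T against WT in mESC, het against parental in both states and ATRA against mESC in WT.

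**Figure D1:**
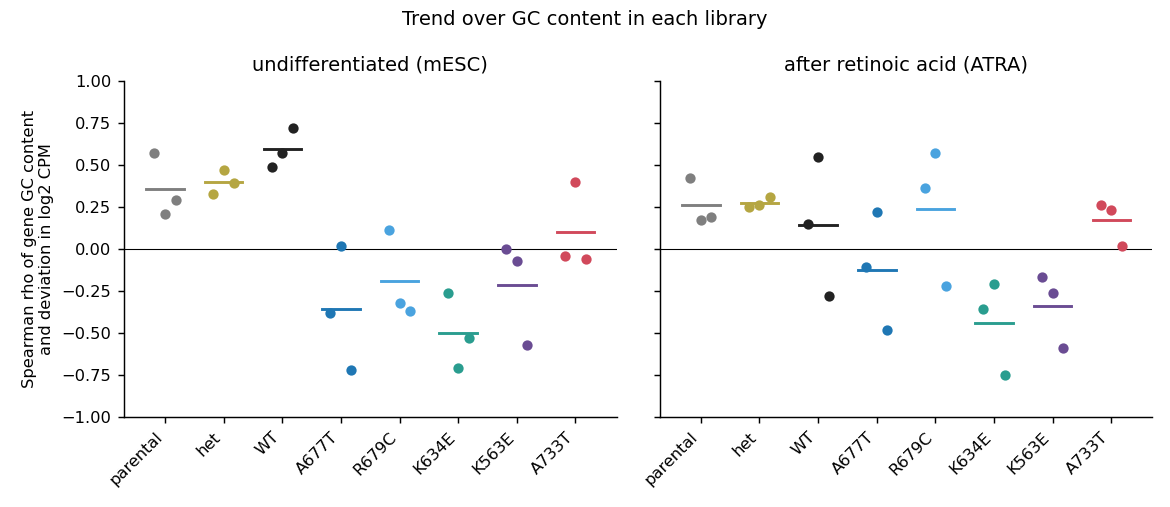
Spearman correlation across genes (vertical axis, no unit) between gene GC content and each library's deviation in log2 CPM, for every line in mESC (left) and ATRA (right), with points for libraries (n = 3 per line) and bars for means.

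Ezh2 transcripts were fewest in the het line in both states and more numerous in WT. The gene lies on chromosome 6 from 47530139 to 47595341 (GRCm38). In mESC its level was 301.8 ± 0.87 CPM (SD, n = 3) in parental cells, 280.6 ± 4.11 in het, 439 ± 22.8 in WT and 361 ± 17.6 in A733T, and the mean of the 4 other variants ran from 489 ± 22.2 in R679C to 560 ± 49.6 in A677T. After ATRA it was 279 ± 5.02 CPM in parental cells, 239 ± 4.86 in het, 362 ± 5.04 in WT and 275 ± 3.76 in A733T. The labels do not say whether reads of the added EZH2 are counted under Ezh2, so these levels are not those of the endogenous alleles alone.

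Against het, Ezh2 was higher in WT by 0.65 in mESC (SE 0.068, adjusted p = 2.11e-07) and by 0.61 in ATRA (SE 0.057, adjusted p = 1.53e-08). Het fell by 0.23 below parental in ATRA (adjusted p = 0.0109), a call lost without het replicate 3 (0.0607) or parental replicate 2 (0.0672) and with no filter on low counts (0.0628), and stood at -0.11 in mESC (adjusted p = 0.562). These are 0.852 and 0.927 of the parental level, above the 0.5 that loss of 1 allele alone would give, and counts by exon, which would show the deleted part, were not analysed here. The mean of the 4 variants exceeded WT by 0.29 in mESC (SE 0.054, adjusted p = 0.000112) and by 0.18 in ATRA (SE 0.045, adjusted p = 0.00422). Singly, A677T (0.39), K634E (0.32) and K563E (0.26) exceeded WT in mESC, and K563E (0.23) did so in ATRA. R679C passed in mESC at 0.19 (adjusted p = 0.0428) but lost its call without any 1 of 5 libraries, which were R679C replicates 1 (0.122), 2 (0.189) and 3 (0.0884) and WT replicates 2 (0.0881) and 3 (0.274), and with the GC correction (0.308). In ATRA, A677T stood at 0.19 (adjusted p = 0.0154), and at 0.118, 0.0589 and 0.053 without A677T replicate 3, WT replicate 1 and WT replicate 2. K634E stood at 0.23 (adjusted p = 0.00801), and at 0.0685 without K634E replicate 3 and 0.0636 with the GC correction. A733T was lower than WT by log2 values of -0.40 in ATRA (SE 0.057, adjusted p = 1.47e-05) and -0.26 in mESC (adjusted p = 0.00676, or 0.0525 without WT replicate 1).

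Among the other core subunits, Ezh1 fell in the 4 variants in mESC (-0.21, adjusted p = 0.0111, but 0.0711 without WT replicate 2 and 0.0907 with the GC correction), while Eed stood at 0.10 (0.0757) and Suz12 at 0.12 (0.347). In ATRA none of Eed (-0.06), Suz12 (-0.24) and Ezh1 (-0.15) passed. Of the 15 PRC2 subunits and cofactors measured in mESC, 5 rose in the 4 variants and 3 fell. Aebp2 (0.50) was among those that rose, and Phf19 (-0.64, at adjusted p = 0.0655 in replicates 1 and 2 alone and 0.135 with A733T averaged in) and Phf1 (-0.61) fell. The PRC2 list as a whole did not pass (adjusted p = 0.455 in mESC and 0.943 in ATRA), nor did the PRC1 list, in which 8 of 23 members rose and 7 fell in mESC (0.511).

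**Figure D2:**
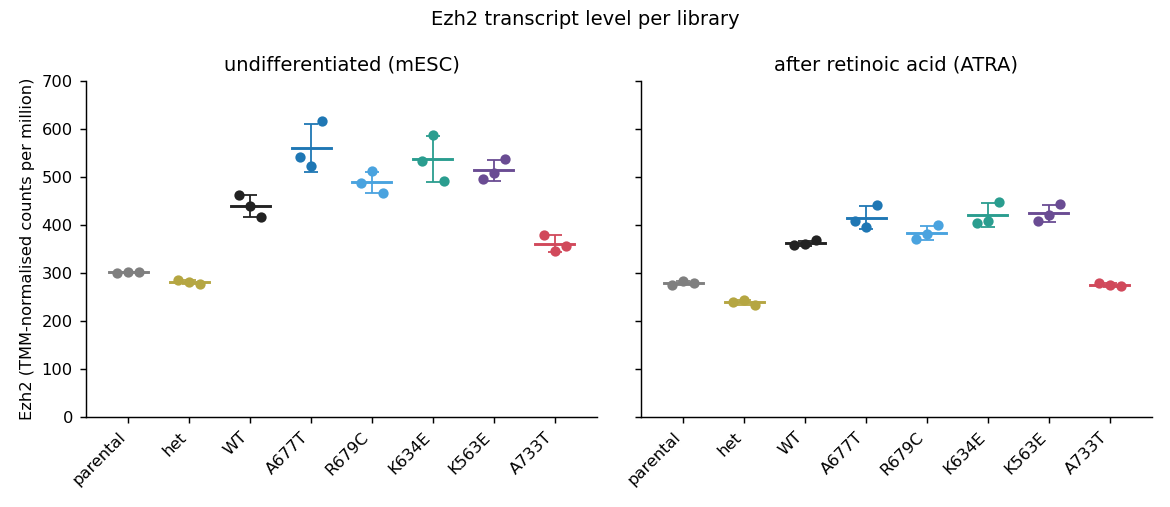
Ezh2 level in TMM-normalised CPM (vertical axis, from 0) in every line in mESC (left) and ATRA (right), with points for libraries, horizontal bars for means and error bars for SD (n = 3).

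The effect of removing 2i and LIF and adding ATRA was first read in the WT line. Genes known to be induced by retinoic acid rose, as did Hox genes, and genes of naive pluripotency fell. Cyp26a1, which encodes the enzyme that degrades retinoic acid, went from 0.099 ± 0.080 CPM to 369.5 ± 37.4 CPM (SD, n = 3). Of the 30 retinoic acid response genes measured, 28 rose, among them Zfp703 (7.97) and Stra8 (5.96). Of 33 Hox genes, 27 rose and 3 fell. Hoxb1, Hoxb5, Hoxb2 and Hoxb3 had 0 counts in mESC and were at least 2380-, 1070-, 443- and 380-fold higher after ATRA, and Hoxb6, also at 0 counts, reached 32.4 CPM, while Hoxa5 rose 3980-fold (95% counting interval 1100 to 32900) and Hoxa3 1370-fold (470 to 6660). Csn3 and Grm6 were at least 1830- and 202-fold higher.

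Of 29 naive pluripotency genes, 23 fell and 4 rose. The transcription factor genes Klf4 (-6.18), Tfcp2l1 (-4.90), Esrrb (-4.48) and Prdm14 (-8.04) fell, as did Tdh (-6.76), the gene of threonine dehydrogenase. Other large decreases were in Trpm1 (1210-fold, interval 217 to 47700), Hoxc12 (121-fold, 21.7 to 4780), AC141882.2 (at least 24.3-fold lower), Lrrc34 (-7.06), Vax2os (-6.86) and Xaf1 (-6.65). Primed epiblast genes rose in 13 of 18 cases, such as Dnmt3a (2.99) and Sox4 (3.08). Endoderm markers rose in 18 of 25, led by the transcription factor genes Gata6 (8.67) and Sox17 (6.66). Developmental Polycomb targets rose in 44 of 69, germline genes in 26 of 33, imprinted genes in 26 of 45, such as Peg10 (4.91) and Cdkn1c (4.83), and 2-cell-like genes in 19 of 21.

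In all, 5271 genes were higher and 5164 lower of 17683 tested, with 2864 and 1500 at least 2-fold changed. The retinoic acid (adjusted p = 1.5e-65), naive (1.76e-65), Hox (6.47e-51), endoderm (4.27e-13), primed (4.93e-08), germline (2.54e-06), imprinted (9.91e-06), Polycomb target (3.71e-05) and 2-cell-like (0.00933) lists also passed with an estimated correlation, at an adjusted p of at most 0.0272. The fibroblast list passed with 13 of 18 members higher (0.00275), but stood at adjusted p = 0.072 with an estimated correlation, and 0.0107 with that and the GC correction, under which the 2-cell-like list stood at 0.0613. Eed (-0.97, adjusted p = 1.11e-19), Ezh1 (-0.47) and Ezh2 (-0.28) fell, and Suz12 stood at -0.01 (adjusted p = 0.951).

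The het line, labelled as having 1 Ezh2 allele deleted, was compared with parental. The clearest difference was the loss of Meg3, Rian and Mirg, noncoding transcripts of the imprinted Dlk1-Dio3 region on chromosome 12, between 109541001 and 109749460. In mESC, Rian was 2260-fold lower (95% counting interval 625 to 18600), Meg3 841-fold (288 to 4080) and Mirg 254-fold (45.6 to 10000). In ATRA, Meg3 was 1720-fold lower (308 to 67900), Mirg at least 69.7-fold lower and Rian lower by -7.61 (SE 0.272). The sum of the 3 transcripts was 111 to 123 CPM in the parental libraries in mESC and 61.6 to 67.0 CPM in ATRA, and at most 0.395 and 0.944 CPM in any library of the 7 other lines.

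Other imprinted genes were lower as well. The imprinted list holds these 3 transcripts, and with them 12 of 40 members fell in mESC and none rose (adjusted p = 1.57e-43, and 2.58e-09 with an estimated correlation). With the 3 left out, a test added after the result was seen, 9 of 37 fell in mESC and none rose (4.51e-11, and 1.91e-05 estimated), and 10 of 41 in ATRA (6.69e-06, and 0.000383). H19 fell by 1.99 and Cdkn1c, which encodes a cell-cycle inhibitor, by 1.45. After ATRA, 20 of the 21 2-cell-like genes fell (adjusted p = 3.47e-128, and 1.1e-10 estimated). Zscan4d, a member of a multi-copy family whose reads may be shared between copies, went from 8.66 ± 0.63 CPM to 0.380 ± 0.112 (SD, n = 3), and Zscan4b fell by 5.88. Serpina3m fell in mESC (-3.15). Trpm3 (1.80), Insl3 and Ccnd2 (1.17) rose in mESC, as did Bcl11a (1.56, though at adjusted p = 0.0555 in replicates 1 and 2 alone). Crct1, Kcnj8 (1.35), Abcc9 (1.33) and Cxcl12 (1.30) rose in ATRA. Of these, Ccnd2, Kcnj8, Abcc9 and Cxcl12 lie on chromosome 6, as does Ezh2, and the median log2 fold change over the genes of that chromosome was 0.08 in mESC and 0.09 in ATRA, against -0.02 to 0.02 and -0.03 to 0.03 on each other chromosome. The changes of these genes and of Ezh2 were not separated from that shift. The p53 and stress list fell in both states, with 5 of 27 members lower in mESC and 8 in ATRA (adjusted p = 1.61e-07 and 1.05e-06, and 0.00294 and 0.00521 estimated).

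In mESC, 186 genes were higher and 358 lower of 15830 tested, and the number of genes changed, mESC het vs parental, was 324, 360 and 354 without het replicate 3, parental replicate 2 and parental replicate 3, 321 in replicates 1 and 2 alone, 1002 with the GC correction and 1141 with the replicate block as well, against 544. In ATRA, 374 were higher and 690 lower of 17030, and 805 and 968 with the GC correction. In the count of genes changed, ATRA het vs parental, 1064 became 632 without het replicate 1 and 2089 with the GC correction and the block.

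**Figure D3:**
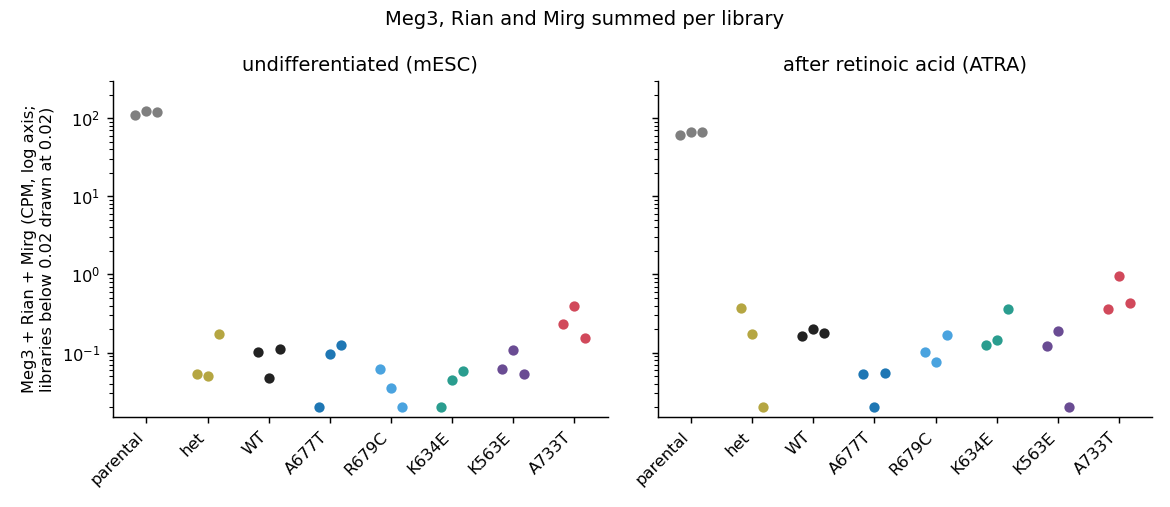
Sum of Meg3, Rian and Mirg in TMM-normalised CPM (vertical log axis) in every line in mESC (left) and ATRA (right), with points for libraries (n = 3 per line) and those under 0.02 CPM drawn at 0.02.

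Adding wild-type EZH2 was read from WT against het. After ATRA, developmental genes were higher in WT than in het. Of 31 Hox genes, 17 rose and none fell, or 19 adjusted over the list alone (adjusted p = 2.85e-16, and 0.000421 with an estimated correlation), such as Hoxa5 (0.74), Hoxa9 (1.02), Hoxa10 (1.20) and Hoxb8 (0.91). Developmental Polycomb targets rose in 23 of 64 and fell in 4 (3.31e-08, and 0.00466 estimated), led by Gata2 (1.62), Cdx2 (1.58) and Msx1 (1.32). Tal1 and Fli1, transcription factor genes of blood and endothelium, rose by 2.41 and 2.39, and Kdr, which encodes a VEGF receptor, by 2.38. Endoderm markers rose in 13 of 25 (1.54e-07, and 0.017 estimated), with Sox17 at 0.96 and Gata6 at 0.59. The 2-cell-like genes rose in 12 of 21 (2.28e-10, and 0.000421 estimated), such as Zscan4a (2.28), which the annotation lists as an unprocessed pseudogene.

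Several stress genes were lower in WT than in het. After ATRA, Chac1 (-3.21), Atf3 (-1.99) and Asns (-0.73), genes of the integrated stress response, fell, as did Pck2 (-2.08), Cntnap3 (-2.72) and Ly6g5c (-2.21). The p53 and stress list had 4 of 27 members higher and 11 lower, with a median of 0.06 and a mean of -0.37, and its test pointed down (1.22e-05, and 0.0126 with an estimated correlation). In mESC it had 2 higher and 12 lower (5.19e-05, and 0.0483 estimated), with Chac1 at -1.27 and Psat1 at -0.49. The largest mESC changes were in Filip1 (2.92), Foxd1 (2.91), C78283 (2.12) and Sox3 (1.77), and in Slc7a11 (-2.83), a cystine transporter gene, Inhbe (-1.81) and Slc16a9 (-1.71). Pcdhga8 (-1.69) lost its call without het replicate 2 (0.0874), WT replicate 1 (0.0683) or WT replicate 2 (0.0757). Genes that depend on LIF, ERK or WNT signalling rose in 8 of 25 and fell in 2 (2.87e-06), among them Spry4 (1.01) and Myc (1.01), though at adjusted p = 0.0948 with an estimated correlation, and 0.0131 with that and the GC correction.

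In mESC, 826 genes were higher and 1083 lower, and 1746 and 1523 with the GC correction. In the count of genes changed, mESC WT vs het, 1909 became 1218, 1080 and 1153 without het replicates 2 and 3 and WT replicate 1, 1135 in replicates 1 and 2 alone and 3530 with the GC correction and the block. In ATRA, 1301 were higher and 1488 lower, and 2235 and 1991 with the GC correction. The number of genes changed, ATRA WT vs het, was 2789, and 1849 and 1752 without het replicate 3 and WT replicate 3, 4226 with the GC correction and 4720 with the block as well. Ezh1 stood at -0.33 in ATRA (adjusted p = 0.0106, but 0.0883 and 0.0729 without het replicate 3 and WT replicate 3).

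The effect of Weaver syndrome variants was read from the mean of A677T, R679C, K634E and K563E against WT. In mESC, many more genes were strongly lower than strongly higher, with 723 at least 2-fold lower and 160 at least 2-fold higher. Endoderm markers fell as a list and primed epiblast genes rose, though each list stood at adjusted p = 0.125 with an estimated correlation, and at 0.0364 with that and the GC correction. Meis2, a homeobox gene on chromosome 2 from 115863064 to 116065839, rose by 2.53 (SE 0.243, adjusted p = 5.87e-09), from 0.815 ± 0.043 CPM in WT to between 2.62 ± 0.74 in A677T and 6.75 ± 0.64 in R679C (SD, n = 3). Msln, which encodes mesothelin and lies on chromosome 17 from 25748613 to 25754378, fell by 3.17 (SE 0.274, adjusted p = 8.7e-10), from 1.73 ± 0.10 CPM in WT to at most 0.311 ± 0.080.

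The other large increases were in Hs6st2 (2.12), Itga1 (2.02), Zfp934 (1.85), Zfp951 (1.85), the Wnt ligand gene Wnt8a (1.84), the homeobox gene En1 (1.79), Prrg1 (1.72), the neurofilament gene Nefl (1.65) and Ror1 (1.61). Besides Msln, the largest decreases were in Vwf (-2.64), which encodes von Willebrand factor, Hoxc4 (1.16 CPM in WT and 0.04 to 0.47 CPM in the variants), Tlx2 (-2.60), Tspo2 (-2.56), Fndc1 (-2.46), Foxd1 (-2.43), Mir142hg (-2.40), Ace (-2.37) and Igsf21 (-2.36). Among the 1211 genes higher in all 4 variants, the strongest calls were Vim (1.16), which encodes vimentin, Nefl, Gja1 (1.17), Crybg3 (1.05) and Zic2 (0.63). Among the 1244 lower in all 4, they were Pou2f3 (-1.94), Sh3rf2 (-1.96), Islr2 (-1.77), Alpk3 (-1.59) and Arhgap30 (-1.75). With the GC correction, 1064 genes were higher and 801 lower in all 4.

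Endoderm markers fell in 14 of 20 cases and rose in 3 (adjusted p = 1.11e-05, but 0.125 with an estimated correlation, and 0.0364 with that and the GC correction). Lama1, which encodes a laminin chain, fell by 1.07 (SE 0.058), and the collagen IV genes Col4a2 and Col4a1 by 1.37 and 0.99. Primed epiblast genes rose in 10 of 18 and fell in 2 (adjusted p = 0.00118, but 0.125 with an estimated correlation, and 0.0364 with that and the GC correction), led by Lef1 (1.24), an effector of WNT signalling, Zic2 (0.63), Sox4 (0.63) and Zic5 (0.65). Skeletal genes fell in 13 of 23 and rose in 3 (adjusted p = 0.0379, but 0.125 with an estimated correlation and 0.105 with the GC correction). Fgfr3, which encodes a receptor that restrains bone growth, fell by 1.63, and the BMP antagonist gene Chrd by 1.07. That call was also lost without any 1 of 8 libraries, with the highest value without A677T replicate 3 (0.0991).

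Growth genes moved both ways. Of 42 growth control genes, 12 rose and 10 fell (adjusted p = 0.774). The growth factor genes Vegfa (-1.54), Pdgfb and Tgfa (-2.19) fell, as did Igfbp4 (-1.61). Imprinted genes rose in 7 of 40 and fell in 11 (0.507), with Grb10, which restrains growth, at -0.92, Phlda2 at -1.08, Slc22a18 at -1.80 and Peg10 at 0.70. Of 22 overgrowth syndrome genes, 8 rose and 4 fell (0.474), with Nfix at -1.38. Among 9 Hox genes, 4 fell and none rose (0.0742), including Hoxc12 (-2.07). The remaining lists also did not pass, at an adjusted p of 0.0742 for neuroectoderm (8 higher and 3 lower of 19, but 0.015 with the GC correction, and 0.0364 with that and an estimated correlation), 0.242 for proliferation (12 and 5 of 30), 0.261 for p53 and stress (8 and 12 of 27), 0.359 for interferon (1 and 3 of 10) and for LIF, ERK and WNT signalling (9 and 6 of 25, but 0.000891 with the GC correction, and 0.109 with that and an estimated correlation), 0.474 for naive pluripotency (5 and 11 of 29), 0.507 for fibroblasts (1 and 8 of 13), 0.905 for Polycomb targets (10 and 13 of 36), 0.924 for retinoic acid response (5 and 10 of 21), and 0.995 for mesoderm (3 and 3 of 16), trophoblast (6 and 7 of 16) and germline (5 and 5 of 26). Of the 2 members of the 2-cell-like list measured in mESC, none passed (0.924).

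In all, 3395 genes were higher and 3629 lower of 15830. With the GC correction 3211 were higher and 2813 lower, of which 120 and 485 were at least 2-fold changed. The number of genes changed, mESC mean of 4 variants vs WT, was 7024, and 4665 in replicates 1 and 2 alone.

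Taken 1 at a time in mESC, Meis2 was the largest increase in R679C (3.07), K634E (2.37) and K563E, and Zfp951 in A677T (2.83). Next came Prrg1 (2.58) and Cyyr1 (2.56) in A677T, En1 (2.30) and Itga1 (1.94) in R679C, Hs6st2 (2.23) and Zfp934 (1.90) in K634E, and Hs6st2 (2.64) and Itga1 (2.47) in K563E. The largest decreases were Foxd1 (-4.99), Hoxc4 (30.6-fold, 95% counting interval 8.47 to 253) and Ace (-4.57) in A677T, Chil1, Tspo2 (-3.19) and Msln (-3.02) in R679C, Tlx2 (-2.99), Msln (-2.42) and Mir142hg (-2.08) in K634E, and Jdp2 (-3.48), Hoxc4 (-3.27) and Rac2 (-3.14) in K563E. Endoderm markers fell in 12, 11, 11 and 13 of 20 in A677T, R679C, K634E and K563E, at an adjusted p of at most 0.000329, but with an estimated correlation at 0.153, 0.115, 0.0891 and 0.113. Neuroectoderm markers rose in K563E, with 8 of 19 higher and 3 lower (0.00243, and 0.0334 estimated).

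Genes higher and lower numbered 3553 and 3508 in A677T, 1758 and 1993 in R679C, 2296 and 2339 in K634E, and 2657 and 2810 in K563E. With the GC correction they were 2044 and 1687 in R679C, 1605 and 1448 in K634E, and 3067 and 2387 in K563E. Of genes changed, mESC A677T vs WT, there were 7061, and 4197 in replicates 1 and 2 alone and 5246 without A677T replicate 3, which stood apart from its group. For genes changed, mESC K563E vs WT, the count was 5467, and 3479 in replicates 1 and 2 alone. Of genes changed, mESC R679C vs WT, there were 3751, and 2241 in replicates 1 and 2 alone and 2357, 2390 and 2279 without R679C replicates 2 and 3 and WT replicate 3. The number of genes changed, mESC K634E vs WT, was 4635, and 2490 and 2518 without K634E replicate 2 and WT replicate 3, and 3053 with the GC correction.

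After ATRA, endoderm genes were lower in the mean of the 4 variants than in WT. Of 25 endoderm markers, 18 fell and 1 rose, or 19 and 1 adjusted over the list alone (adjusted p = 5.22e-28, and 0.000154 with an estimated correlation). Gata6, on chromosome 18 from 11052064 to 11085635, was at 78.7 ± 2.44 CPM in WT and at 33.1 ± 1.73 to 46.8 ± 1.03 CPM in the variants (SD, n = 3), a decrease by -1.04 (SE 0.055, adjusted p = 1.4e-13). Gata4 (-1.13), Sox17 (-1.13), Foxa2 (-1.45), Lama1 (-1.20) and Pdgfra (-0.99) also fell. Hox genes fell in 10 of 31 and rose in 1 (adjusted p = 1.76e-05, and 0.0498 with an estimated correlation, or 0.11 with that and the GC correction), led by Hoxb9 (-1.06), Hoxa7 (-0.96), Hoxb8 (-0.65) and Hoxb6 (-0.67). Cdkn1c, an imprinted inhibitor of the cell cycle, was at 68.4 ± 4.83 CPM in WT, 16.9 ± 0.92 in A677T, 33.2 ± 4.61 in R679C, 38.7 ± 2.92 in K563E and 40.2 in K634E.

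Other genes with large decreases were Sh3rf2 (-2.96, SE 0.215, adjusted p = 7.51e-11), the Wnt ligand genes Wnt3a (-2.72) and Wnt7b (-1.83), Ndrg1 (-2.51), Slc25a34 (-2.22), Slc38a5 (-1.80), Emp1 (-1.79), Ndufa4l2 (-1.74), Tcf23 (-1.72) and Pla1a (-1.71). The largest increases were in Mir670hg (1.89), Cyp2b23 (1.85), Itgb8 (1.55), Id4 (1.52), C1qtnf3 (1.51), Slco1a5 (1.45), Wnt3 (1.40), Zfp988 (1.39), Themis (1.35) and Calb1 (1.35). The strongest calls among the 226 genes higher in all 4 variants were Ankrd6 (0.69), Pou4f3 (1.35), Map1b (0.91), Sall3 (0.82) and Irs2 (0.65), and among the 387 lower in all 4 they were Lama1, Foxn4 (-1.70), Gata6, Zfp57 (-0.86) and Lefty2 (-1.08).

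The 2-cell-like genes fell in 8 of 21 (adjusted p = 0.000394, and 0.0474 with an estimated correlation), such as Zscan4a (-1.67). Naive pluripotency genes fell in 12 of 29 and rose in 5 (0.00329, but 0.0849 estimated), with Tfcp2l1 at -0.90, Klf5 at -0.66 and Esrrb at -0.51, and primed epiblast genes rose in 9 of 17 with none lower (0.000149, but 0.0849 estimated), with Lef1 at 0.53 (adjusted p = 0.0815 with A733T averaged in) and Cdh2 at 0.48. Germline genes fell in 9 of 33 (0.0093, but 0.215 with an estimated correlation, 0.0357 with that and the GC correction, and 0.071 with A733T averaged in), led by Stra8 (-0.78). The p53 and stress genes rose in 9 of 27 (0.0259, but 0.205 estimated), with Plk2 at 0.62. Tested as list p53_stress, ATRA mean of 4 variants vs WT, they stood at 0.0502 without WT replicate 3.

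The lists that did not pass in ATRA were imprinted genes (2 higher and 8 lower of 44, adjusted p = 0.0817), neuroectoderm (7 and 2 of 24, 0.0817), Polycomb targets (10 and 14 of 64, 0.102), skeletal genes (4 and 13 of 33, 0.135), mesoderm (3 and 4 of 21, 0.309), proliferation (2 and 0 of 30, 0.312), PRC1 (5 and 0 of 23, 0.319), fibroblasts (1 and 7 of 17, 0.485), retinoic acid response (8 and 8 of 30, 0.588), growth control (12 and 8 of 45, 0.588), overgrowth syndrome (3 and 3 of 22), trophoblast (5 and 3 of 18) and interferon (2 and 1 of 10, each 0.613), and LIF, ERK and WNT signalling (7 and 7 of 24, 0.949). Their strongest members included Sfmbt2 (-1.10) and Mest (0.50) among imprinted genes and Ptch1 (0.53) and Runx1 (-1.06) among skeletal genes.

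In all, 1435 genes were higher and 2062 lower of 17030, of which 68 and 319 were at least 2-fold changed. With the GC correction 2492 were higher and 2170 lower. The number of genes changed, ATRA mean of 4 variants vs WT, was 3497, and 2318 and 2001 without WT replicates 1 and 2, and 1717 with A733T averaged in.

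In ATRA, endoderm markers below WT were 16 of 25 in A677T, 15 in R679C, 16 in K634E and 18 in K563E. In each, 1 was higher (adjusted p at most 3.46e-14, and 0.00663 estimated). These tests share WT libraries, in which this list exceeded het. Hox genes fell in A677T, with 18 of 31 lower and none higher (1.52e-18, and 0.000477 estimated), and Hoxb9 at 10.3 ± 1.33 CPM there against 36.6 ± 1.95 in WT (SD, n = 3). In K634E, 7 Hox genes fell and 2 rose (0.00434, but 0.198 with an estimated correlation and 0.12 with the GC correction), and the list did not pass in R679C (6 higher and 8 lower, 0.179) or K563E (6 and 8, 0.561). Imprinted genes fell in A677T (12 of 44, with none higher, 1.79e-05, and 0.000692 estimated), and naive genes in K634E (13 of 29, with 1 higher, 7.66e-07, and 0.0103 estimated). Naive genes also fell in R679C (10 of 29, with 4 higher, 0.000485, but 0.0678 estimated) and K563E (10, with 5 higher, 0.000657, but 0.059), where the latter values were 0.0399 and 0.0498 with the GC correction, while in A677T 7 were higher and 4 lower, the test pointed up and the list did not pass (0.332). Lists were not tested between variants. Sh3rf2 was among the 3 largest decreases in R679C (-2.76), K634E (-2.96) and K563E (-3.50), next to Wnt3a (-3.03, -2.56 and -3.01), with Ndrg1 in R679C (-3.40) and K563E (-3.58) and Tcf23 in K634E (-1.97). In A677T these were Zscan4a (-3.35), Slc25a34 (-3.02) and Calb2 (-2.97). The largest increases were Zfp951 (2.19), Klhl13 (1.99) and Cyp2b23 (1.92) in A677T, Mir670hg (1.85), Wnt3 (1.69) and Cyp2b23 (1.68) in R679C, Gbp2 (1.99), Mir670hg (1.93) and Itgb8 (1.90) in K634E, and Mir670hg (2.42), Itgb8 (2.14) and Cyp2b23 (2.06) in K563E.

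Genes higher and lower numbered 1419 and 1882 in A677T, 830 and 928 in R679C, 1256 and 1302 in K634E, and 1453 and 2030 in K563E, and with the GC correction 2575 and 2149 in A677T, 1644 and 1331 in R679C, 1339 and 1160 in K634E, and 2389 and 1985 in K563E. The number of genes changed, ATRA R679C vs WT, was 1758, and 2975 with that correction and 3459 with the block as well, and that of genes changed, ATRA A677T vs WT, was 3301 and 5097 with both. Of genes changed, ATRA K563E vs WT, there were 3483, and 2207 and 2145 without K563E replicate 3 and WT replicate 2. Of genes changed, ATRA K634E vs WT, there were 2558, and 1180 without K634E replicate 3, which stood apart from its group, 1677 and 1247 without WT replicates 1 and 2, and 3910 with the replicate block.

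Whether a variant does more than the loss of 1 allele was asked by comparing the mean of the 4 variants with het. These lines are het with EZH2 added, and wild-type EZH2 alone moved several of these genes the same way against het, such as Chac1 (-1.27), Sox3 (1.77) and Ccnd2 (1.67) in mESC and Kdr (2.38) and Fli1 (2.39) in ATRA, so the changes below are not those of the variants alone. In mESC, endoderm markers fell below het in 14 of 20 and rose in 2, primed epiblast genes rose in 10 of 18 and fell in 1, and p53 and stress genes fell in 13 of 27 and rose in 10 (adjusted p = 3.27e-06, 3.27e-06 and 0.000259, and 0.0461 for each with an estimated correlation). That last call stood at 0.0512 with no filter on low counts. Lama1 fell by 1.64, Chac1 by 3.09 and Vegfa by 2.27, and Lef1 (1.99), Sox3 (2.04) and Ccnd2 (2.75) rose. En1 (3.94), Wnt8a, Evx1 (3.11) and Btla (2.88) rose most, and Jdp2 (-3.71), Vwf (-3.67), Fhad1 (1.04 CPM in het and 0.02 to 0.24 CPM in the variants) and Grin1 (-3.59) fell most. After ATRA, Pcdh12 (3.28), Chl1 (3.16), Kdr (3.09) and Fli1 (3.09) rose most, and Fut1, Wnt3a (-3.60), Ly6g5c (-3.60) and Ndrg1 (-3.55) fell most. Fut1 was at 1.74 ± 0.23 CPM in het and 0.0159 to 0.159 CPM in the variants (SD, n = 3). Naive genes fell in 17 of 29 and rose in 7 (9.6e-05), primed genes rose in 11 of 17 and fell in 2 (9.6e-05), and neuroectoderm markers rose in 16 of 24 and fell in 3 (0.00782), though each stood at adjusted p = 0.114 with an estimated correlation. Hox genes were higher than het in 12 of 31 and lower in 2 (0.0114, but 0.185 estimated), and with the GC correction in 14 and 2 (0.0037, but 0.137 estimated). The 2-cell-like genes were higher in 10 of 21 and lower in 2 (0.0406, but 0.185 estimated), a call lost with the GC correction (0.178, with the same 10 and 2), with the replicate block (list two_cell_like, ATRA mean of 4 variants vs het, 0.0782) and without any 1 of 11 libraries. Endoderm markers fell in 15 of 25 and rose in 3 (0.0151, but 0.2 estimated), and germline genes fell in 14 of 33 and rose in 1 (0.00141, but 0.121, or 0.0353 with the GC correction as well). In mESC 3864 genes were higher and 4224 lower, and in ATRA 3546 and 4247. With the GC correction there were 4454 higher and 3929 lower in mESC and 4440 and 4078 in ATRA.

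A733T, taken here as the growth restriction-associated variant, differed from WT for many genes in the direction opposite to the 4 other variants. In mESC, 436 genes were at least 2-fold higher and 69 at least 2-fold lower. The most increased were Igf2os (4.37, SE 0.546) and Igf2 (3.55, SE 0.650, adjusted p = 0.000301), which encodes an imprinted growth factor and lies on chromosome 7 from 142650766 to 142666816. The pair overlaps on opposite strands, so reads of one may count for the other. Igf2 was low in every line, at 1.46 ± 0.74 CPM in A733T and 0.120 ± 0.078 in WT (SD, n = 3). Imprinted genes rose in 14 of 40 and fell in 2 (adjusted p = 5.22e-06, and 0.0032 with an estimated correlation), among them Grb10 (1.29), Cdkn1c (1.97) and H19 (1.48). Hox genes rose in 7 of 9 with none lower (6.82e-05, and 0.0032 estimated), such as Hoxb9 (1.70) and Hoxd13 (1.59).

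Lists of lineage markers also rose in A733T in mESC. Endoderm markers rose in 8 of 20 with none lower (0.000174), including Dab2 (2.19), Gata4 (1.46) and Lrp2 (0.94), trophoblast markers in 9 of 16 with 1 lower (0.00371), including Krt8 (0.92) and Gata2, and germline genes in 12 of 26 with 1 lower (0.000433), including Tex15 (1.25) and Dmrt1 (1.36), each at adjusted p = 0.0486 with an estimated correlation. Skeletal genes rose in 7 of 23 with 1 lower (0.00166, and 0.0204 estimated), such as Comp (1.72) and Col2a1 (1.22), and p53 and stress genes in 12 of 27 with 1 lower (0.000316, and 0.0361 estimated), such as Atf3 (1.36) and Gdf15 (0.84). Neuroectoderm markers rose in 6 of 19 (0.0166, but 0.0609 without A733T replicate 2) and Polycomb targets in 12 of 36 (0.0166, but 0.141 without A733T replicate 2 and 0.283 with an estimated correlation, or 0.0395 with that and the GC correction). Genes that depend on LIF, ERK or WNT signalling fell in 8 of 25 and rose in 2 (1.31e-06, and 0.0486 estimated), with Spry4 at -1.37, Myc at -0.93 and Etv4 at -1.09. Primed genes fell in 4 of 18 (0.00163, but 0.0995 estimated), with Zic2 at -1.10 and Sox3 at -1.69. Vim fell by 1.42 and the naive gene Dppa3 rose by 2.17.

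Other large increases in mESC were in Cdc42ep1 (3.12), Pramel6 (2.86), Ky (2.63), Slc16a9 (2.40), AA467197 (2.36) and Flrt1 (2.33), and the largest decreases Tgm3 (-2.83), BB123696 (-2.19), Notumos (-1.97), Bcl11a (-1.97), Btla (-1.86), Filip1 (-1.84), Pou4f2 (-1.83), Nkx1-2 (-1.83), Robo4 (-1.79) and Notum (-1.78). Notumos and Notum lie beside each other, so their reads may not be separable. In all, 1686 genes were higher and 1367 lower, but 1964 and 2125 with the GC correction. Of genes changed, mESC A733T vs WT, there were 3053, and 1960, 2002 and 2025 without A733T replicate 1, A733T replicate 3 and WT replicate 3.

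After ATRA, A733T exceeded WT in Hox and other patterning genes. Hox genes rose in 17 of 31 and fell in 3, or 18 and 4 adjusted over the list alone (adjusted p = 9.51e-11, and 0.00305 with an estimated correlation). Hoxc9 (2.86), Hoxc8 (2.58) and Hoxd9 (2.31) rose most, and Hoxb9, the most abundant of those named, went from 36.6 ± 1.95 CPM in WT to 97.0 ± 5.97 in A733T (SD, n = 3). Polycomb targets rose in 23 of 64 and fell in 4 (1.75e-08, and 0.00458 estimated), such as Foxc1 (2.58, SE 0.261, adjusted p = 6.56e-08) and Cdx2 (1.66). Trophoblast markers rose in 10 of 18 with 1 lower (7.37e-11, and 0.000153 estimated), including Tfap2c (1.52), Krt8 (1.02) and Dlx3 (1.89). Imprinted genes rose in 16 of 44 with none lower (1.04e-07, and 0.000153 estimated), with Grb10 at 0.85, Peg3 at 1.03, Dlk1 at 1.01, and Cdkn1c at 135 ± 2.61 CPM against 68.4 ± 4.83 in WT.

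The p53 and stress genes rose in 16 of 27 with 1 lower (2.07e-12, and 0.000388 with an estimated correlation), led by Chac1 (2.46), Atf3 (1.97) and Asns (0.67). Neuroectoderm markers rose in 11 of 24 with 1 lower (0.000229, and 0.0155 estimated), including Pax6 (0.43) and Irx3 (1.03), and 2-cell-like genes in 5 of 21, or 14 adjusted over the list alone (0.000266, and 0.00874 estimated). Mesoderm markers rose in 7 of 21 and fell in 3 (0.0133, but 0.0547 with the replicate block), with Kdr at -0.96 and Tal1 at -0.67. Passing only with the preset correlation were endoderm (8 higher and 1 lower of 25, with 0.112 estimated), germline (9 and 1 of 33, 0.0975), growth control (18 and 5 of 45, 0.0709), skeletal (11 and 1 of 33, 0.0655), proliferation (1 and 7 of 30, 0.0811), PRC2 (1 and 4 of 15, 0.0811) and primed genes (1 and 3 of 17, 0.193), where each last value is the adjusted p with an estimated correlation. With the GC correction too, this was 0.028 for germline, 0.0104 for skeletal and 0.0312 for PRC2 genes. Of endoderm markers, Gata6 stood at -0.41 and Krt19 at 1.25. The signalling list had 2 members higher and 5 lower of 24, with a median of 0.03, a mean of -0.06 and a test that pointed down (0.0286, but 0.278 with an estimated correlation, 0.0606 with the replicate block, and 0.0548 and 0.0701 without A733T replicate 1 and WT replicate 2).

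The other largest increases in ATRA were Cntnap3 (2.62), Tmprss2 (2.31), Slc4a1 (2.21), Lad1 (2.13) and Ebf4 (2.08), and the largest decreases Filip1 (-1.83), Crct1 (-1.71), Prr22 (-1.44), Mep1b (-1.39), Shcbp1l (-1.33), A2m (-1.26), Rfx4 (-1.25), Sall1 (-1.24) and Ctrl (-1.19). Platr5 (-1.25) lost its call without A733T replicate 1 (0.0653), A733T replicate 2 (0.0539) or WT replicate 3 (0.0744). In all, 1766 genes were higher and 1248 lower, and 2094 and 2613 with the GC correction. In the count of genes changed, ATRA A733T vs WT, 3014 became 5128 with that correction and the block.

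Set directly against the mean of the 4 variants, A733T was higher in Hox, endoderm and imprinted genes in both states. In mESC, all 9 Hox genes rose (adjusted p = 3.22e-05, and 0.00456 with an estimated correlation), as did 15 of 20 endoderm markers with 2 lower (4.61e-09, and 0.00834), 19 of 23 skeletal genes with 3 lower (8.59e-05, and 0.00688) and 20 of 40 imprinted genes with 8 lower (0.000193, and 0.00967), and primed genes fell in 10 of 18 and rose in 4 (3.22e-05, and 0.0394), where the last value of each is the adjusted p with an estimated correlation. In ATRA, 22 of 25 endoderm markers rose and 2 fell (5.24e-17, and 0.000871), as did 21 of 31 Hox genes with 3 lower (3.5e-13, and 0.00198), 41 of 64 Polycomb targets with 7 lower (1.42e-06, and 0.011), 25 of 44 imprinted genes with 4 lower (1.85e-06, and 0.000661) and 17 of 21 2-cell-like genes (3.88e-06, and 0.00313). In mESC, Igf2os, Cdc42ep1, Ky (4.55) and Igf2 rose most, with Igf2os at 1.51 ± 0.63 CPM in A733T and 0 to 0.101 CPM in the 4 variants, and Cdc42ep1 at 3.12 ± 0.35 and 0.04 to 0.15 CPM (SD, n = 3). Ucma (0.05 CPM in A733T and 0.61 to 1.17 CPM in the variants), Tgm3 (-3.68), Robo4 (-3.24) and Btla (-3.15) fell most. In ATRA, Fut1, Hoxd9 (3.94), Hoxc9 and Foxc1 (3.60) rose most, and Gabrg1 (-2.72), Spink10 (-2.72), Cyp2b23 (-2.47) and Chl1 (-2.47) fell most. In mESC 4246 genes were higher and 3724 lower, with 1633 and 204 at least 2-fold changed, and in ATRA 4601 and 3654, with 1488 and 222. With the GC correction more genes were lower than higher, at 4225 higher and 4589 lower in mESC and 4425 and 4885 in ATRA, while those at least 2-fold changed were 1461 and 241 in mESC and 1255 and 252 in ATRA.

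**Figure D4:**
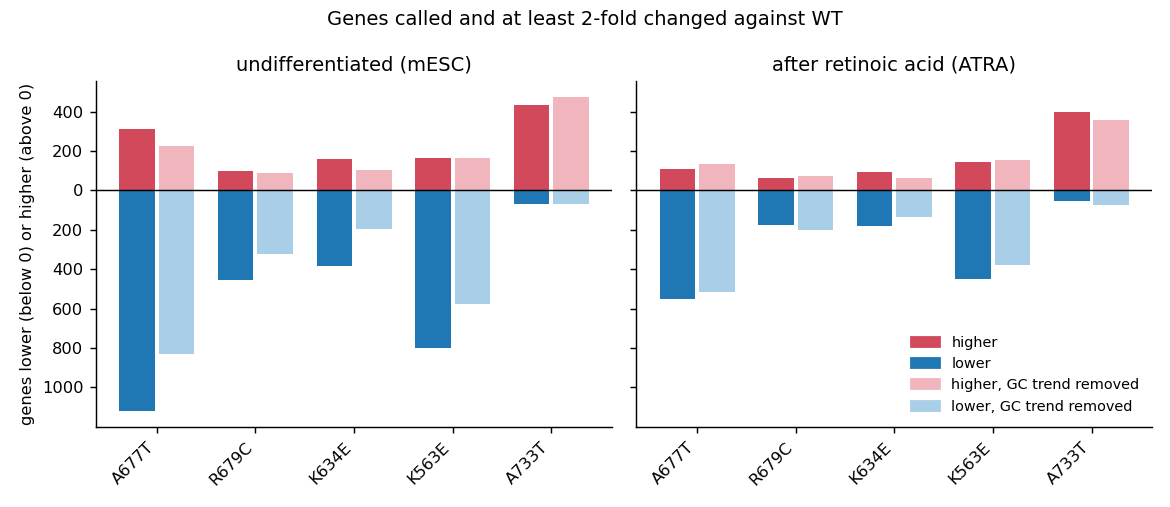
Number of genes at least 2-fold higher or lower than WT (bars from 0) for A677T, R679C, K634E, K563E and A733T, in mESC and ATRA, from 3 libraries per line, with dark bars for the counts as tested and light bars for those with the GC trend taken out.

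Similarity between variants was measured across genes, as the correlation of their log2 fold changes against the shared WT libraries. In mESC the 6 pairs among A677T, R679C, K634E and K563E had r from 0.75 to 0.83, and the 4 pairs with A733T from -0.12 to 0.04. Unchanged simulated groups, which share a simulated control and hold no GC trend, gave 0.48. In ATRA the values were 0.56 to 0.71 and -0.18 to -0.07, against 0.48 in simulated groups. These values depend on the treatment of genes with low counts. The mean r in mESC and ATRA was -0.06 and -0.13 with A733T, but 0.33 and 0.35 with DESeq2 and 0.38 and 0.39 with no filter, and among the 4 it was 0.78 and 0.62, but 0.56 and 0.51, and 0.54 and 0.50. Simulated groups were not run under DESeq2 or with no filter, so these values show no similarity beyond the shared controls and no lack of it. Over genes of at least 10 CPM in ATRA, R679C with K634E had r = 0.44, against 0.49 in simulated groups. The covariance exceeded the simulated one by 0.144 to 0.249 in mESC and 0.056 to 0.112 in ATRA among the 4, and lay below it with A733T by values from -0.065 to -0.026 and from -0.072 to -0.048. Over genes of at least 10 CPM in mESC, A733T had a covariance of 0.014 with A677T and 0.015 with K634E, above the simulated 0.006, and of -0.003 with R679C and -0.005 with K563E, below it. Of the 1211 genes higher in all 4 variants in mESC, A733T was lower in 137 and higher in 105, and of the 1244 lower in all 4, it was higher in 317 and lower in 92. In ATRA, of 226 higher genes A733T was lower in 69 and higher in 19, and of 387 lower genes it was higher in 158 and lower in 19.

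Whether the variants act differently after ATRA was tested by the interaction of the mean of the 4 variants with ATRA. Meis2 and Vim rose more in mESC than in ATRA. Meis2 rose by 2.53 in mESC and 0.51 in ATRA, an interaction of -1.99 (SE 0.205, adjusted p = 1.65e-09), and Vim rose by 1.16 and 0.40 (interaction -0.73, SE 0.073). Rassf4 changed sides, at 0.12 to 0.42 CPM in the variants against 1.39 ± 0.30 in WT in mESC and at 7.06 to 11.4 CPM against 4.06 ± 0.51 in ATRA (SD, n = 3), an interaction of 3.28 (SE 0.294, adjusted p = 5.4e-11). Ndrg1 stood at -0.27 in mESC and -2.51 in ATRA (interaction -2.21, SE 0.254), and Zfp57, which maintains imprints, at -0.05 and -0.86 (interaction -0.77, SE 0.074). The interaction was positive for 802 genes and negative for 448, and for 664 and 682 with the GC correction. The number of genes changed, interaction of mean of 4 variants vs WT with ATRA, was 1250, and 762 and 760 without ATRA WT replicate 3 and mESC WT replicate 3, and 829 in replicates 1 and 2 alone.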

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

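The genes below responded to the 4 variants differently in mESC and in ATRA, by a test of the interaction with ATRA. The tests of the GC trend and of the Ezh2 amount in this part were chosen only after the results were seen, and the splits of libraries before. Among genes named for a rise in mESC, the interaction was below 0 for Meis2 (-1.99), Hs6st2 (-1.88), Itga1 (-1.75), Wnt8a (-1.62), Nefl (-1.04), Vim (-0.73), Gja1 (-0.84), Crybg3 (-0.87) and Zic2 (-0.55). Among those named for a fall there, it was above 0 for Vwf (1.54), Hoxc4 (2.38), Tlx2 (2.24), Tspo2 (1.72), Fndc1 (1.61), Foxd1 (2.25), Ace (0.92), Pou2f3 (0.59), Islr2 (0.89) and Alpk3 (0.91). Among genes named for their change in ATRA, the interaction was above 0 for Mir670hg (3.25), Id4 (1.76), Map1b (0.40), Sall3 (0.35) and Irs2 (0.45), which rose there, and below 0 for Sh3rf2 (-0.96), Wnt3a (-1.32), Ndrg1 (-2.21), Slc25a34 (-1.18), Emp1 (-0.76), Zfp57 (-0.78) and Lefty2 (-0.43), which fell. The direction is not general, since Map1b and Sall3 also rose in mESC, and Sh3rf2, named for its fall in mESC as well, Wnt3a, Slc25a34 and Emp1 also fell there. Named for the interaction itself were Rassf4 (3.28), Aadac (4.47), Vstm2b (4.47) and Lhx1 (3.58), and Nostrin (-3.30), Lrrc31 (-2.25) and Evx1 (-2.05).

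These 38 genes, of which 19 were above and 19 below 0, had adjusted p-values from 5.4e-11 in Rassf4 to 0.0496 in Slc25a34, and 35 passed with the GC correction, where Ace stood at 0.0784, Sall3 at 0.204 and Irs2 at 0.171. Genes picked for a large change in 1 state are prone to a smaller change in the other, so the sizes for those are not unbiased. Hoxc4, Mir670hg, Aadac, Vstm2b, Lhx1, Nostrin, Lrrc31 and Evx1 had at most 3 counts in some group, and their values are fitted, depend on the prior count and are no bounds. In all, 1250 genes passed the interaction test, a number only the real split of 25 reached (highest other 6). Splits mix lines, so chance differences between lines stay open.

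Some calls rested on 1 library. The adjusted p of Aadac, interaction of mean of 4 variants vs WT with ATRA, was 0.0207, and 0.061, 0.071 and 0.0877 without ATRA WT replicates 1, 2 and 3 (range over alternatives 0.0106 to 0.0963). For Lhx1, interaction of mean of 4 variants vs WT with ATRA, it was 0.0343, and 0.0503 without ATRA WT replicate 1 and 0.127 and 0.125 without mESC WT replicates 1 and 2 (0.0247 to 0.127). For Lrrc31, interaction of mean of 4 variants vs WT with ATRA, it was 0.0276, and 0.0575 and 0.102 without ATRA WT replicates 1 and 2 (0.0168 to 0.102). For Nostrin, interaction of mean of 4 variants vs WT with ATRA, it was 0.0322, and 0.0573, 0.0626, 0.122 and 0.135 without ATRA WT replicate 2, mESC K563E replicate 3, mESC WT replicate 1 and mESC WT replicate 2 (0.0173 to 0.135). Evx1, interaction of mean of 4 variants vs WT with ATRA, stood at 0.0445 and lost its call without any 1 of 12 libraries, with the highest values without ATRA WT replicates 1 (0.212) and 2 (0.193) (0.00855 to 0.212). Wnt3a, interaction of mean of 4 variants vs WT with ATRA, stood at 0.00655 and ranged from 0.000256 to 0.0639, the highest without ATRA WT replicate 2.

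A pair of gene lists also differed between states in the effect of the variants. The p53 and stress genes were shifted upward in ATRA relative to mESC, with a median interaction of 0.19, 7 of 27 members above 0 and 0 below, or 12 and 2 adjusted over the list alone (adjusted p = 0.000524, but 0.117 with an estimated correlation, and 0.0287 with that and the GC correction). Genes that depend on LIF, ERK or WNT signalling were shifted downward, with a median of -0.09, 1 of 25 above 0 and 5 below (adjusted p = 0.0432, but 0.485 with an estimated correlation, and 0.011 with that and the GC correction). The call of list signalling_2i_LIF, interaction of mean of 4 variants vs WT with ATRA, was lost without any 1 of 10 libraries, with the highest values without ATRA K634E replicate 3 (0.184) and mESC A677T replicate 2 (0.137), and ranged over all alternatives from 2.58e-07 to 0.184.

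A733T and the 4 other variants had different effects, with 7970 genes changed between them in mESC and 8255 in ATRA. In each state only the real split of 25 reached that number (highest others 1278 and 2426), which leaves chance differences between lines open. Among genes higher or lower in all 4 variants, A733T was called on the opposite side of WT more often than on the same side, for 454 against 197 genes in mESC.

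A GC trend as the whole cause is argued against by a ratio of opposite to same-side calls of 3.8 in mESC with the trend taken out, against 2.3 before, and of 4.45 against 5.97 in ATRA. On a score where the 4 variants average 0.466 to 0.669 in mESC and WT 0, A733T, het and parental lay at -0.144, -0.05 and -0.139, and in ATRA at -0.163, -0.042 and -0.207. A733T lay outside the span from het to WT by at least 8.55 SD of its 3 libraries in either state, but parental, which carries no variant and whose Ezh2 level also lies between theirs, lay outside it too, so a smaller amount of Ezh2 transcript cannot be told apart from differences between lines. Also open and untested are that A733T may change PRC2 activity in the other direction, a hypothesis found on the same data, and differences that arose when the lines were made, which the design ties to the variant.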

How the results depend on the processing

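Most values of named genes and gene lists kept their call, or stayed uncalled, under the alternatives. The GC correction, alone or with the replicate block, replicates 1 and 2 alone, and the imprinted list without Meg3, Rian and Mirg were chosen after seeing the data, the other alternatives before. Over the alternatives other than leaving out 1 library, 15236 values of named genes held direction and call, 253 lost the call, 234 gained it and 4 reversed, and of the lists' values 3689 held, 69 lost and 158 gained it. Leaving out 1 library, 18202, 516 and 89 values of genes held, lost and gained the call, as did 4485, 82 and 53 of lists. Counts of genes stayed within 1.5 times in 155 of the values and left that range in 23, and in 184 and 26 without 1 library. Ezh2 held in 165, lost its call in 11 and gained it in 2, and in 198 and 12 without 1 library. Similarity held in 16 and moved in 20, and in 54 and 18 without 1 library. Settings with fewer libraries have less power by construction, and for the other changes below the cause was not tested. With every mESC library thinned to the 15361598 counts of the smallest, 3286 genes were higher and 3413 lower in the 4 variants of 15253 tested, against 3395 and 3629 of 15830.

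Of genes changed, ATRA A677T vs WT, there were 3301, and 5097 with block and GC correction. For genes changed, ATRA A733T vs WT, the count was 3014, and 4707 with the GC correction and 5128 with block and GC correction. Counting genes changed, ATRA het vs parental, gave 1064, and 1773 with the GC correction, 2089 with block and GC correction and 632 to 841 without 1 library. Of genes changed, ATRA K563E vs WT, there were 3483, and 2145 to 3373 without 1 library. For genes changed, ATRA K634E vs WT, the count was 2558, and 3910 with the block and 1180 to 3239 without 1 library. Counting genes changed, ATRA mean of 4 variants vs WT, gave 3497, and 1717 with A733T averaged in and 2001 to 3668 without 1 library. Of genes changed, ATRA R679C vs WT, there were 1758, and 2975 with the GC correction and 3459 with block and GC correction. For genes changed, ATRA WT vs het, the count was 2789, and 4226 with the GC correction, 4720 with block and GC correction and 1752 to 2581 without 1 library. Counting genes changed, interaction of mean of 4 variants vs WT with ATRA, gave 1250, and 829 in replicates 1 and 2 and 760 to 1729 without 1 library. Of genes changed, mESC A677T vs WT, there were 7061, and 4197 in replicates 1 and 2. For genes changed, mESC A733T vs WT, the count was 3053, and 1960 to 2836 without 1 library. Counting genes changed, mESC het vs parental, gave 544, and 1002 with the GC correction, 1141 with block and GC correction, 321 in replicates 1 and 2 and 324 to 376 without 1 library. Of genes changed, mESC K563E vs WT, there were 5467, and 3479 in replicates 1 and 2. For genes changed, mESC K634E vs WT, the count was 4635, and 3053 with the GC correction and 2490 to 4429 without 1 library. Counting genes changed, mESC mean of 4 variants vs WT, gave 7024, and 4665 in replicates 1 and 2. Of genes changed, mESC R679C vs WT, there were 3751, and 2241 in replicates 1 and 2 and 2279 to 3335 without 1 library. For genes changed, mESC WT vs het, the count was 1909, and 3269 with the GC correction, 3530 with block and GC correction, 1135 in replicates 1 and 2 and 1080 to 1649 without 1 library.

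Ezh2 changed as follows, as log2 values with the adjusted p in brackets. The Ezh2 transcript level, ATRA A677T vs WT, was 0.19 (0.0154), and 0.20 (0.0652) with no filter and 0.15 to 0.22 without 1 library (0.0144 to 0.118). For the Ezh2 transcript level, ATRA het vs parental, the value was -0.23 (0.0109), and -0.22 (0.0628) with no filter and -0.24 to -0.21 without 1 library (0.0284 to 0.0672). The Ezh2 transcript level, ATRA K634E vs WT, was 0.23 (0.00801), and 0.11 (0.0636) with the GC correction and 0.17 to 0.26 without 1 library (0.0075 to 0.0685). For the Ezh2 transcript level, ATRA mean of 4 variants vs WT, the value was 0.18 (0.00422), and 0.067 (0.399) with A733T averaged in. The Ezh2 transcript level, ATRA R679C vs WT, was 0.089 (0.359), and 0.12 (0.0244) with the GC correction and 0.12 (0.0158) with block and GC correction. For the Ezh2 transcript level, mESC A733T vs WT, the value was -0.26 (0.00676), and -0.32 to -0.22 without 1 library (0.007 to 0.0525). The Ezh2 transcript level, mESC K563E vs WT, was 0.26 (0.00363), and 0.18 (0.0585) in replicates 1 and 2. For the Ezh2 transcript level, mESC R679C vs WT, the value was 0.19 (0.0428), and 0.15 (0.0598) with all 48 libraries in 1 fit, 0.069 (0.308) with the GC correction, 0.18 (0.0972) with no filter, 0.069 (0.253) with block and GC correction, 0.17 (0.102) in replicates 1 and 2, 0.18 (0.0568) with RLE factors and 0.13 to 0.22 without 1 library (0.0401 to 0.274).

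A pair of genes crossed 0. The change of Cdx1, mESC K634E vs WT, was -0.45, and 0.001 with the GC correction and 0.002 with block and GC correction. The change of E2f1, mESC A677T vs WT, was -0.38, and 0.006 with the GC correction and 0.005 with block and GC correction. Similarity, as mean r over pairs, moved as follows. The similarity of variants, ATRA, pairs among the 4 variants, was 0.62, and 0.51 with DESeq2, 0.50 with no filter and 0.56 to 0.68 without 1 library. For the similarity of variants, ATRA, pairs with A733T, the value was -0.13, and -0.05 with all 48 libraries in 1 fit, 0.35 with DESeq2, -0.26 for genes of at least 10 CPM, 0.39 with no filter, 0.01 in replicates 1 and 2 and -0.11 to 0.04 without 1 library. The similarity of variants, mESC, pairs among the 4 variants, was 0.78, and 0.68 with all 48 libraries in 1 fit, 0.56 with DESeq2, 0.73 with the GC correction, 0.87 for genes of at least 10 CPM, 0.54 with no filter, 0.73 with block and GC correction, 0.68 in replicates 1 and 2 and 0.73 to 0.79 without 1 library. For the similarity of variants, mESC, pairs with A733T, the value was -0.06, and 0.09 with all 48 libraries in 1 fit, 0.33 with DESeq2, -0.13 with the GC correction, 0.06 for genes of at least 10 CPM, 0.38 with no filter, -0.13 with block and GC correction and -0.06 to 0.11 without 1 library.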

Other observations

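Further gene lists were lower in het than in the parental line. Of the tests in this part, those of the GC trend, of het in place of WT, and of Meg3, Rian and Mirg were chosen only after the results were seen, and the gene lists, the thinning of libraries and the splits before. Against parental, het was lower after ATRA in germline genes (11 of 33 lower and 0 higher, adjusted p = 1.44e-10, and 0.00373 with an estimated correlation), trophoblast markers (10 of 18 lower and 1 higher, adjusted p = 1.05e-06, and 0.00237 estimated), naive pluripotency genes (11 of 29 lower and 2 higher, adjusted p = 6.69e-06, and 0.00747 estimated), mesoderm markers (5 of 21 lower and 0 higher, adjusted p = 0.000881, and 0.00513 estimated) and Polycomb targets (17 of 64 lower and 3 higher, adjusted p = 1.72e-05, and 0.0218 estimated). In mESC, Hox genes (3 of 9 lower and 0 higher, adjusted p = 4.09e-05, and 0.00294 estimated) and trophoblast markers (5 of 16 lower and 1 higher, adjusted p = 2.11e-06, and 0.00413 estimated) were lower. Naive pluripotency genes went the other way in mESC, with a median log2 fold change of 0.075 and 0 of 29 higher or lower (adjusted p = 0.0184, but 0.214 estimated), and with the GC correction 5 were higher and 1 lower. That call of list naive_pluripotency, mESC het vs parental, was lost without het replicate 1 (0.146) or parental replicate 3 (0.0864).

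On the first principal component, means of the lines in mESC were -46.1 ± 2.4 in parental, -42 ± 2.3 in A733T, -30.6 ± 1.9 in het, -14.9 ± 3.3 in WT, 22.9 ± 3.7 in K634E, 28.3 ± 2.8 in R679C, 38.9 ± 5.7 in K563E and 43.6 ± 10.8 in A677T (SD, n = 3). In ATRA they were -53.4 ± 1.8, -36.2 ± 2.9, -27.6 ± 2.8 and -3.3 ± 7.2 in the first 4 of these, and 22.9 ± 7.9 in R679C, 26.9 ± 11.4 in K634E, 30.3 ± 6.4 in A677T and 40.4 ± 4.5 in K563E.

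In mESC, the 4 variants had more genes at least 2-fold lower than WT than at least 2-fold higher, 723 against 160. With the GC trend taken out, 4.04 genes were lower per gene higher, with all 24 libraries thinned to 15361598 counts 4.33, and against het instead of WT 5.58, which argues against the GC trend, library depth or an odd WT line as the whole cause. The variants' effect on PRC2 may be the source, but histone methylation was not measured in these libraries, and differences between lines that arose when they were made stay open. Neither was tested.

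Meg3, Rian and Mirg were expressed in the parental line and near 0 in the 7 others, in both states. Library depth is argued against by the highest library of another line, at 1.53 percent of the lowest parental one. Loss across 1000000 bases on either side is argued against by the 19 and 21 other genes there. Their median log2 fold change was 0.04 in mESC and 0.017 in ATRA (median absolute deviation 0.155 and 0.138). Dio3 fell in mESC (-1.88), and Dlk1 (-0.68) and Rtl1 (-1.95) in ATRA, so loss within the Dlk1-Dio3 region stays open. Silencing of these transcripts in the cell that founded the het line is a candidate, since all 7 lines derive from it. An effect of the deleted allele stays open too. None was tested, and the WT line, with EZH2 added back, had not regained them.

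Libraries were split into groups of the same sizes to ask whether a chance division gives as many changed genes. Where 25 splits were run, only the real one reached the real number. Splits mix lines, so chance differences between lines stay open. Real and highest others were 7024 and 3796 for mESC mean of 4 variants vs WT. They were 8088 and 2844 for mESC mean of 4 variants vs het. For ATRA mean of 4 variants vs WT they were 3497 and 1807, and for ATRA mean of 4 variants vs het 7793 and 1497. For groups of 3 against 3, the 10 splits are too few for a share under 0.05, and 1 of 10 reached the real number. Real and highest other numbers in mESC were 7061 against 0 for mESC A677T vs WT, 3751 against 0 for mESC R679C vs WT, 4635 against 0 for mESC K634E vs WT, 5467 against 1 for mESC K563E vs WT, 3053 against 0 for mESC A733T vs WT, 544 against 0 for mESC het vs parental and 1909 against 0 for mESC WT vs het. In ATRA they were 3301 against 0 for ATRA A677T vs WT, 1758 against 1 for ATRA R679C vs WT, 2558 against 0 for ATRA K634E vs WT, 3483 against 0 for ATRA K563E vs WT, 3014 against 0 for ATRA A733T vs WT, 1064 against 4 for ATRA het vs parental and 2789 against 0 for ATRA WT vs het, and between states 10435 against 0 for ATRA vs mESC in WT.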
